A study of Homo sapiens with 7 samples.

How the data were processed

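Expression was measured in 7 biopsies of human diaphragm, the main muscle of inspiration. Per the labels, 3 biopsies came from patients with chronic obstructive pulmonary disease (COPD) who had lung volume reduction surgery, and 4 control biopsies came from patients operated on for isolated pulmonary nodules. Total RNA of each biopsy was read on 1 oligonucleotide array with Affymetrix probe set names. The groups were taken from the sample titles, which number the COPD biopsies 5, 6 and 8 and the controls 1 to 4. The labels do not state that each biopsy came from a different person, so the p-values of single genes measure the spread between these arrays.

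The authors deposited 1 table of signal intensity on a linear scale, with 22283 probe sets and 7 columns, all of which were used. The software, background correction and scaling that the authors used are not given in the sources used here. The deposited intensities were positive throughout. In 6 columns the 2%-trimmed mean lay between 148 and 150.1, while in COPD replicate 5 it was 248. The lowest and the highest trimmed mean differed by 67.3%. Depth in the sense of counted molecules does not apply to arrays; their number, 7, limits the precision.

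The rules for scaling, filtering and testing, the gene lists and the rule for naming genes were fixed before the data were examined. Because the trimmed means differed by more than 10%, the intensities were quantile normalized across the 7 arrays. Values under the 20th percentile of all values (an intensity of 23.4, or 4.55 on the log2 scale) were set to it, and log2 was taken. A probe set was kept where at least 3 of 7 arrays lay above their own 40th percentile. The 68 control probe sets were left out, and so were 55 probe sets of genes linked to donor sex, which were neither tested nor reported. This left 14259 probe sets. No detection calls were used here.

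Gene names came from the platform annotation. Of all probe sets, 19071 named 1 gene, 1043 named several and 2169 had no name there. For 19059 of the 19071 the Entrez identifier was found in a RefSeq gene table of assembly GRCh38.p14, used for names only, which changed 0 symbols. Each gene was represented by its kept single-gene probe set with the highest mean over the 7 arrays, which gave 8776 genes. Of these, 2548 had several kept probe sets, and in 1175 of the 2548 at least 1 other probe set had a difference of the opposite sign. TRIM63 and FBXO32 of the atrophy list had no probe set under their names in the annotation used here and were not analysed here.

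COPD and control were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend; 5 residual and 4.57 prior degrees of freedom), with all 7 arrays and no covariate. Benjamini-Hochberg adjusted p under 0.05 was the threshold, two-sided. Differences are COPD minus control on the log2 scale, with the moderated standard error (SE). Of 41 gene lists, 40 had at least 5 measured genes, and 680 of the 866 listed genes were measured. The Schwann and nerve marker list had 2 and was not tested. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, following the variance trend of the fit, and p was adjusted over the 40 lists. At that preset the p-value takes a list's genes as nearly independent, so it does not measure the spread of the list between arrays. The estimated correlation was 0.53 for the immediate early list and 0.57 for the metallothionein list. It was 0.68 for respiratory complexes II to IV and 0.77 for complex I. The same lists were run with an estimated correlation and with fry, which tests whether a list's genes move one way on balance. A list score per array was the mean of the members' log2 values after subtracting each member's mean over the arrays. Scores, the difference between the slow and the fast fibre lists, and the log2 ratio of the 3' to the 5' control probe sets of GAPDH and beta-actin were compared with an exact two-sided permutation test over the 35 splits of the arrays, for which the smallest possible p is 0.0286.

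Genes were named by this rule: genes past the threshold with groups that do not overlap, filled up to 24 by smallest p; the 4 members of smallest p of each list past its test and of the slow and fast fibre lists; and up to 2 members of other lists described. Probe sets with several genes and genes whose level can reveal a donor's genotype were not named.

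The accession numbers of the samples form 3 groups: controls 1 to 3 with COPD replicate 6, COPD replicates 5 and 8, and control 4 alone. By plan the last 2 groups were joined into 1 later run of 3 arrays, set against the earlier run of 4, although control 4 stands apart from COPD replicates 5 and 8 in these numbers. Values within the later run and with the run as a block rest on that joining. A block of all 3 groups was added after the data were seen, on counts, lists and the fibre index. It leaves COPD replicate 6 against controls 1 to 3, so its means equal those within the earlier run. The labels name no batch. The run was used as a technical block, and differences were also taken within each run. Hybridization controls, transcripts of bacteria and a phage with 9 probe sets, gave a second technical measure. The mean score of the 12 lists of other cell types was added as a covariate after the data were seen, and its effect is not given for those 12 lists, which make up the score. Further alternatives changed the scaling, the floor, the filter, the probe set rule, the moderation and the arrays included. With 1 array left out, and with another scaling or floor, the genes and probe sets chosen on all 7 arrays were held. Leaving out 1 array was also run with both chosen anew on the arrays left.

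The tests were run on simulated data with the means and residual spread of the 8776 genes, 200 of them shifted, in 20 simulations with independent noise. For this comparison the test recovered 19.95% of genes shifted by 1 on the log2 scale and 72.5% of those shifted by 2, with a mean of 4.2 false calls per simulation. A list of the size of the immediate early list, shifted by 0.7, was called in 20 of 20 simulations, and a mean of 0.05 other lists was called with it. The simulated genes were independent of each other, which the real ones are not. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.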

Results

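The 7 diaphragm biopsies fell into 3 from patients with COPD, a chronic obstruction of the airways that loads the inspiratory muscles, and 4 controls. The design holds 1 comparison, COPD against control, which asks how transcript levels in the diaphragm differ between the groups. The median deposited intensity per array ran from 77.2 in control 1 to 95.2 in control 4, with 146.02 in COPD replicate 5. After normalization, the most similar arrays were control 1 and COPD replicate 6 (Pearson r = 0.935 across genes, which are not independent replicates). The least similar were control 1 and control 4 (r = 0.758 across genes). The first principal component held 36.7% of the variance and set control 4 (52.5) apart from the other arrays (-31.6 to 7.05).

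No single gene passed the adjusted threshold between COPD and control. Of 8776 genes, 0 passed adjusted p in limma (lowest 0.9996). An unadjusted p under 0.05 was reached by 210 genes, 81 higher and 129 lower in COPD, where chance would give 438.8. That count was 355 without control 1 and 394 without COPD replicate 6, and 649 with the deposition run as a block, with 0 past adjusted p in each. The groups did not overlap in 318 genes, or 3.62%, where chance gives 5.71%. The median SE of a difference was 0.286 on the log2 scale, and the number of arrays limits the precision.

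The gene of smallest p was the metallothionein MT1M, a small metal-binding protein, at 7.83 ± 0.66 (SD, n = 4) in the controls and 5.20 ± 0.95 (SD, n = 3) in COPD. That was at least 6.23-fold lower in COPD, a log2 difference of -2.64 (95% interval -3.71 to -1.56, limma adjusted p = 0.9996), with 1 of 3 COPD values at the floor. The difference was -1.68 with the higher floor of the 40th percentile. The other genes named here were taken by smallest p, and each had the same limma adjusted p. Log2 differences below 0 were measured for the glycolytic regulator PFKFB3 (-2.07, SE 0.62), the cytokine IL6 (-1.26, SE 0.35) and the receptor tyrosine kinase KIT (-1.49, SE 0.42). Among regulators of transcription, values were -1.37, SE 0.36 for ID1, -1.36, SE 0.39 for CEBPD, -1.05, SE 0.26 for BACH1 and -1.03, SE 0.31 for NR4A1. Lower means in COPD were also measured for BCL7A (-1.52), GNB3 (-1.50), CARHSP1 (-1.30), the apoptosome scaffold APAF1 (-1.22), TSPAN8 (-1.04), SLCO4A1 (-0.98) and LDB2 (-0.76). Without COPD replicate 6, KIT was -0.95, and without COPD replicate 8, BCL7A was -0.94, and with the higher floor, GNB3 was -0.53 and CARHSP1 -0.64. With probe sets averaged, NR4A1 was -0.21 and BCL7A -0.85, and without _x_at and _s_at probe sets, NR4A1 was 0.61.

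Higher means in COPD were measured for NMRK2, a nicotinamide riboside kinase of muscle (1.92, SE 0.54), and for CHRNA1, the alpha subunit of the muscle acetylcholine receptor. CHRNA1 stood at 8.63 ± 0.054 (SD, n = 3) in COPD against 7.66 ± 0.49 (SD, n = 4), which was 1.97-fold higher. Log2 differences were 0.94 for INO80B, 0.89 for SPRYD7, 0.86 for the phosphatase DUSP10, 0.82 for the lipoxygenase ALOX15B, 0.72 for the NF-kB activating kinase IKBKB and 0.64 for the Z-disc protein PDLIM3. The pseudogene FAM86C1P had a mean higher by at least 1.85 against the floor, where 3 of 4 controls lay, and by 0.36 with the higher floor. Of these 24 genes, 9 were higher and 15 lower in COPD, and the groups did not overlap in 23, NMRK2 being the exception. Choice by smallest p favours such genes, and over all genes the share was 3.62%, where chance gives 5.71%. For NR4A1, APAF1 and IKBKB, 1 of 2 probe sets had the opposite sign, with means of -0.21, -0.47 and 0.34 over both, and APAF1 was 0.13 without control 3 when the probe set was chosen anew and the other one stood for the gene, and -0.78 with the higher floor. Of the 113 genes named in all, 62 moved by over 1.5 times with 1 array left out, and 39 of those came nearer to or past 0 by that much without control 4.

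**Figure D1:**
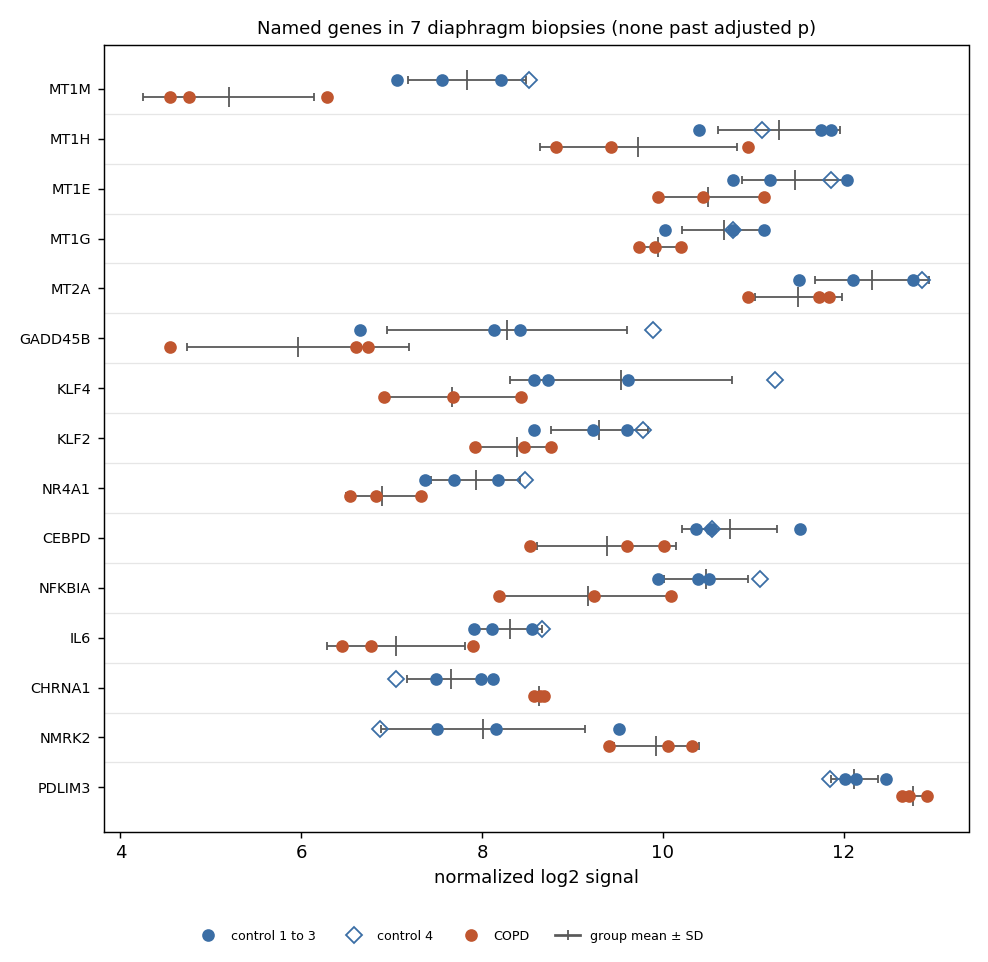
Normalized log2 signal (x axis) of 15 named genes (y axis) in each of the 4 control and 3 COPD arrays, with bars for group mean ± SD and an open diamond for control 4. MT1M lay at 5.20 ± 0.95 in COPD and 7.83 ± 0.66 in controls without overlap, and 0 of the genes shown passed adjusted p.

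Metallothioneins, metal-binding stress proteins, were lower as a list in COPD, with a mean log2 difference of -1.05 and 7 of 8 measured genes below 0 (camera adjusted p = 3.9e-08). The adjusted p was 0.63 with an estimated correlation. MT1M passed when adjusted over the list alone, and 0 members passed over all genes. The next members were MT1H (-1.55, SE 0.51), MT1E (-0.96, SE 0.37) and MT1G (-0.72, SE 0.28). Means within the earlier run, within the later run and with the run as a block were -0.51, -1.40 and -0.93. The mean was -1.02 (camera adjusted p = 2.4e-07, or 0.86 as adjusted p with an estimated correlation) without control 4, and the exact permutation test of its scores gave p = 0.086, or 0.88 adjusted over 40 lists. For this list, past in 16 of 17 alternatives (camera adjusted p 1.8e-11 to 0.17), the call ended with 3 deposition groups (-0.51). Shared probe sequence within this gene family was not tested, 1 of 2 MT1G probe sets had the opposite sign, and without _x_at and _s_at probe sets the list had too few genes for a value. With probe sets averaged, MT1G was -0.28, and without _x_at and _s_at probe sets, MT1G was 0.17.

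Immediate early genes, which cells switch on soon after a stimulus, were lower as a list, with a mean of -0.71 and 21 of 24 measured genes below 0 (camera adjusted p = 1.4e-09, or 0.63 as adjusted p with an estimated correlation). Members included NR4A1, the stress gene GADD45B (at least 4.95-fold lower, a log2 difference of -2.31, 1 of 3 COPD values at the floor) and the transcription factors KLF4 (-1.87, SE 0.61) and KLF2 (-0.91, SE 0.33). Adjusted over the list alone, 0 members passed. Within the earlier run, within the later run and with the run as a block the means were -0.58, -1.56 and -1.04. The score of control 4 was 1.24, and without it the list mean was -0.40 (camera adjusted p = 6.3e-05, or 0.86 as adjusted p with an estimated correlation). GADD45B was then -1.78, or -0.26 when chosen anew, from another probe set. For this list, past in 17 of 18 alternatives (camera adjusted p 2.7e-14 to 0.38), the call ended without _x_at and _s_at probe sets (-0.19). With the other-cell covariate (-0.32), and without control 4 (-0.40), the mean moved over 1.5 times. NR4A1 was 0.61 without _x_at and _s_at probe sets.

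The cytokine and NF-kB list and the interferon list were lower in COPD. The cytokine and NF-kB list had a mean of -0.43 and 14 of 19 measured genes below 0 (camera adjusted p = 1.2e-04, or 0.63 as adjusted p with an estimated correlation), with IL6, the NF-kB inhibitor NFKBIA (-1.30), the neutrophil chemokine CXCL8 (-1.12) and IL1B (-0.72). The interferon list had -0.28 and 16 of 19 measured genes below 0 (camera adjusted p = 0.0018, or 0.63 as adjusted p with an estimated correlation), with IRF9 (-1.41), the peptide transporter TAP1 (-0.93), IFI27 (-0.45) and IRF1 (-0.36). Adjusted over the list alone, 0 members passed in either. With each run taken alone (earlier, then later) and with the run as a block, the means were -0.57, -0.79 and -0.67 for the NF-kB list and -0.10, -0.52 and -0.30 for the interferon list. For the NF-kB list, past in 16 of 18 alternatives (camera adjusted p 6.7e-08 to 0.68), the call ended with the other-cell covariate (-0.14), and without control 4 (-0.26). Without COPD replicate 6 (-0.28), the mean moved over 1.5 times. For the interferon list, past in 14 of 18 alternatives (camera adjusted p 6.0e-04 to 0.54), the call ended without _x_at and _s_at probe sets (-0.19), with 3 deposition groups (-0.10), with the other-cell covariate (-0.17), and without control 4 (-0.22). Without COPD replicate 8, NFKBIA was -0.82, CXCL8 -1.69 and IRF9 -0.90, and without COPD replicate 6, IL1B was -0.38, and with the higher floor, TAP1 was -0.48. With the run block, IL1B was -1.15.

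Glucocorticoid-responsive genes were lower as a list, with a mean of -0.38 and 13 of 16 measured genes below 0 (camera adjusted p = 6.9e-04, or 0.63 as adjusted p with an estimated correlation). The members of smallest p were CEBPD, NFKBIA, MT2A (-0.81) and PDK4 (-1.39), which brakes pyruvate dehydrogenase, and adjusted over the list alone 0 passed. NFKBIA and MT2A also sit in the NF-kB and metallothionein lists. Taken within the earlier run, within the later run and with the run as a block, means were -0.092, -0.091 and -0.092. Without control 4 the mean was -0.56 (camera adjusted p = 4.6e-08, or 0.86 as adjusted p with an estimated correlation). For this list, past in 14 of 18 alternatives (camera adjusted p 4.6e-08 to 0.57), the call ended without _x_at and _s_at probe sets (-0.14), with the run block (-0.092), with 3 deposition groups (-0.092), and without COPD replicate 8 (-0.14). Without control 2 (-0.24) and COPD replicate 6 (-0.60), the mean moved over 1.5 times. Without COPD replicate 8, MT2A was -0.52. With the run block, PDK4 was -0.60.

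The 3 lists of respiratory complexes and ATP synthase were higher in COPD. Complexes II to IV had a mean of 0.29 with 22 of 23 measured genes above 0, complex I 0.26 with 26 of 28 measured genes above 0, and ATP synthase 0.26 with 14 of 15 measured genes above 0. Camera's adjusted p was 1.2e-04, 3.3e-04 and 0.0026, and the adjusted p was 0.63 for each with an estimated correlation. Members of complex I were NDUFAB1 (0.61, SE 0.26), NDUFS1 (0.58), NDUFB8 (0.42) and NDUFB2 (0.37). Others were COX7B (0.50), COX7A2 (0.34) and COX5A (0.49) of complex IV, cytochrome c (CYCS, 0.44), and ATP5MC1 (0.60), ATP5PF (0.48), ATP5MC3 (0.44) and ATP5PB (0.32). Adjusted over the list alone, 0 members passed in any of them. The complex I score was -0.80 in control 4 and -0.20 to 0.39 in the other controls. Means within the earlier run, within the later run and with the run as a block were 0.20, 0.88 and 0.52 for complexes II to IV, 0.26, 0.83 and 0.53 for complex I and 0.12, 0.82 and 0.45 for ATP synthase. For complexes II to IV, past in 16 of 18 alternatives (camera adjusted p 2.1e-10 to 0.96), the call ended with the other-cell covariate (0.00067), and without control 4 (0.067). For complex I, past in 15 of 18 alternatives (camera adjusted p 3.1e-11 to 0.68), the call ended with the other-cell covariate (-0.063), and without control 4 (0.030) and COPD replicate 6 (0.14). Without control 1 (0.42), the mean moved over 1.5 times. For ATP synthase, past in 13 of 18 alternatives (camera adjusted p 6.9e-06 to 0.94), the call ended without _x_at and _s_at probe sets (0.29), with 3 deposition groups (0.12), with the other-cell covariate (-0.00075), and without control 4 (0.066) and COPD replicate 6 (0.23). Without control 1 (0.39), the mean moved over 1.5 times. Without control 4, NDUFS1 was 0.36, NDUFB2 0.23, COX7B 0.30, COX5A 0.19, ATP5PF 0.27, ATP5MC3 0.19 and ATP5PB 0.17, and without control 1, COX5A was 0.74. Without _x_at and _s_at probe sets, NDUFB8 was 0.70 and NDUFB2 0.18, and with the run block, COX5A was 0.77.

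Slow fibre genes and structural sarcomere genes were higher as lists, and the fast fibre list did not pass. The slow fibre list had a mean of 0.23 with 12 of 15 measured genes above 0 (camera adjusted p = 0.025, or 0.63 as adjusted p with an estimated correlation), including phospholamban (PLN, 0.82), the slow light chain MYL3 (0.76), sarcolipin (SLN, 0.28) and the calcium pump ATP2A2 (0.41), for which 1 of 3 probe sets had this sign. The sarcomere list had 0.21 with 17 of 19 measured genes above 0 (camera adjusted p = 0.025, or 0.63 as adjusted p with an estimated correlation), including TMOD1 (0.61), myotilin (MYOT, 0.42), TPM2 (0.40) and LDB3 (0.44). Adjusted over the list alone, 0 members passed in either. The fast fibre list had a mean of 0.20 with 10 of 13 measured genes above 0 (camera adjusted p = 0.054), with CASQ1 at 0.47, TNNI2 at 0.42, MYH4 at 0.80 and MYL1 at 0.18. Within the earlier run, within the later run and with the run as a block the means were -0.13, 0.91 and 0.36 for slow, -0.17, 0.93 and 0.35 for fast and -0.15, 0.95 and 0.37 for sarcomere genes. The fast list passed in 4 of 18 alternatives, with the stricter filter (camera adjusted p = 0.037), the run block (0.0086) and without control 1 (0.017) and control 3 (0.0062), and in 0 with an estimated correlation. For the slow list, past in 9 of 18 alternatives (camera adjusted p 0.0025 to 0.90), the call ended with trimmed mean scaling (0.19), with no filter (0.23), with probe sets averaged (0.20), without _x_at and _s_at probe sets (0.19), with 3 deposition groups (-0.13), with the other-cell covariate (0.021), and without control 4 (0.033), COPD replicate 5 (0.17) and COPD replicate 8 (0.21). For the sarcomere list, past in 10 of 18 alternatives (camera adjusted p 0.0021 to 0.98), the call ended with trimmed mean scaling (0.16), with no filter (0.21), without _x_at and _s_at probe sets (0.18), with 3 deposition groups (-0.15), with the other-cell covariate (0.011), and without control 4 (-0.020), COPD replicate 5 (0.18) and COPD replicate 8 (0.17). Without control 4, PLN was 0.41, MYL3 0.32, SLN 0.17, ATP2A2 0.19, TMOD1 0.29, MYOT 0.26, TPM2 0.20, LDB3 0.14, TNNI2 0.16 and MYH4 0.39, and without COPD replicate 6, MYOT was 0.70, and without control 1, TPM2 was 0.62, and without control 3, MYH4 was 1.28, and with the higher floor, MYH4 was 0.32. With probe sets averaged, ATP2A2 was 0.070 and LDB3 0.29, and without _x_at and _s_at probe sets, ATP2A2 was -0.14, and with the run block, LDB3 was 0.66 and TNNI2 0.65.

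The balance of slow over fast fibre genes did not differ detectably. The mean of the slow genes minus that of the fast genes was 0.72 ± 0.082 (SD, n = 3) in COPD and 0.69 ± 0.17 (SD, n = 4) in controls. The difference was 0.034 on the log2 scale (95% interval -0.24 to 0.31, exact permutation p = 0.86). It was 0.038 within the earlier run and -0.025 within the later run.

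The list of glycolysis and glycogen and that of fatty acid uptake and oxidation were higher in COPD with all arrays, and both turned without control 4. The exact permutation test of the scores gave p = 0.86 for each. The lists of the citric acid cycle and of creatine and adenylate kinases did not pass. Glycolysis and glycogen had a mean of 0.21 with 22 of 27 measured genes above 0 (camera adjusted p = 0.025, or 0.63 as adjusted p with an estimated correlation), with ENO3 (0.69), GPD1 (1.61) and PHKA1 (0.99) above 0 and PFKFB3 below. Fatty acid uptake and oxidation had 0.20 with 20 of 26 measured genes above 0 (camera adjusted p = 0.031, or 0.71 as adjusted p with an estimated correlation). Its members were PPARGC1A (0.73), a regulator of mitochondrial genes, ACAA2 (0.63), UCP3 (-0.85) and CPT1A (-0.33, 2 of 3 probe sets with this sign), and adjusted over the list alone 0 passed in either list. With each run taken alone (earlier, then later) and with the run as a block, the means were -0.020, 0.92 and 0.42 for glycolysis and -0.044, 1.11 and 0.50 for fatty acid genes. For glycolysis, past in 10 of 18 alternatives (camera adjusted p 6.8e-05 to 0.98), the call ended with trimmed mean scaling (0.18), with no filter (0.22), without _x_at and _s_at probe sets (0.40), with 3 deposition groups (-0.020), with the other-cell covariate (-0.036), and without control 4 (-0.033), COPD replicate 5 (0.21) and COPD replicate 6 (0.20). For fatty acid genes, past in 10 of 18 alternatives (camera adjusted p 3.3e-06 to 0.67), the call ended with trimmed mean scaling (0.17), with no filter (0.20), without _x_at and _s_at probe sets (0.14), with 3 deposition groups (-0.044), with the other-cell covariate (-0.13), and without control 4 (-0.11), COPD replicate 6 (0.17) and COPD replicate 8 (0.12). Without control 1 (0.34), control 3 (0.32) and COPD replicate 5 (0.33), the mean moved over 1.5 times. Without control 4, ENO3 was 0.32, GPD1 1.05, PHKA1 0.28, PPARGC1A 0.31, ACAA2 0.29 and UCP3 -1.40, and without COPD replicate 5, UCP3 was -0.53 and CPT1A -0.047, and without COPD replicate 8, CPT1A was -0.50, and with the higher floor, GPD1 was 0.94 and PHKA1 0.65. With probe sets averaged, GPD1 was 0.89, UCP3 -1.30 and CPT1A -0.16, and without _x_at and _s_at probe sets, UCP3 was -1.75, and with the run block, PHKA1 was 1.66, PPARGC1A 1.14 and UCP3 -0.40.

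Genes of muscle development and regeneration were higher as a list, with a mean of 0.42 and 13 of 16 measured genes above 0 (camera adjusted p = 0.0026, or 0.63 as adjusted p with an estimated correlation). Its members were CHRNA1, the cardiac actin ACTC1 (1.29, SE 0.56), the Z-disc protein CSRP3 (0.88) and the myogenic factor MYOD1 (higher by at least 1.10, 1 of 4 controls at the floor). Chaperones had a mean of 0.25 with 17 of 21 measured genes above 0 (camera adjusted p = 0.018, or 0.63 as adjusted p with an estimated correlation), with HSPB7 (0.87), HSPB8 (0.62), HSPA2 (0.49) and DNAJB4 (0.87). Adjusted over the list alone, 0 members passed in either. Taken within the earlier run, within the later run and with the run as a block, means were -0.086, 0.96 and 0.40 for developmental genes and -0.11, 0.72 and 0.28 for chaperones. For developmental genes, past in 14 of 18 alternatives (camera adjusted p 5.5e-04 to 0.54), the call ended with 3 deposition groups (-0.086), with the other-cell covariate (0.30), and without control 4 (0.31) and COPD replicate 5 (0.17). For chaperones, past in 12 of 18 alternatives (camera adjusted p 6.4e-04 to 0.85), the call ended with no filter (0.25), without _x_at and _s_at probe sets (0.23), with 3 deposition groups (-0.11), with the other-cell covariate (0.11), and without control 4 (0.13) and COPD replicate 5 (0.011). Without COPD replicate 5, ACTC1 was 0.58, HSPB8 0.18 and DNAJB4 0.28, and without control 4, CSRP3 was 0.53, HSPB7 0.42 and HSPA2 0.32, and without COPD replicate 6, HSPB8 was 0.98, and without COPD replicate 8, DNAJB4 was 1.39, and with the higher floor, MYOD1 was 0.27.

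Matrix and fibroblast genes were lower as lists, and the matrix list turned without control 4. For the fibroblast list camera's direction, but not the mean, also turned without control 4. Collagens and matrix had a mean of -0.25 with 32 of 41 measured genes below 0 (camera adjusted p = 0.025, or 0.71 as adjusted p with an estimated correlation), with thrombospondin 2 (THBS2, -1.02), periostin (POSTN, -1.19) and TIMP3 (-0.40, 3 of 4 probe sets with this sign) below 0 and THBS4 (0.61) above. The matrix score was 1.75 in control 4 and -0.62 to -0.30 in the other controls, and without control 4 the list was higher in COPD by 0.30 (camera adjusted p = 1.4e-04, or 0.92 as adjusted p with an estimated correlation). Fibroblast markers had -0.31 with 10 of 12 measured genes below 0 (camera adjusted p = 0.046, or 0.63 as adjusted p with an estimated correlation), with C1R (-0.84), SFRP4 (-0.94), C1S (-0.59) and C3 (-0.47). Adjusted over the list alone, 0 members passed in either. Means within the earlier run, within the later run and with the run as a block were 0.082, -1.78 and -0.80 for matrix and -0.18, -1.09 and -0.61 for fibroblast genes. For the matrix list, past in 11 of 18 alternatives (camera adjusted p 4.1e-11 to 0.59), the call ended with no filter (-0.28), without _x_at and _s_at probe sets (-0.15), with 3 deposition groups (0.082), with the other-cell covariate (0.29), and without COPD replicate 6 (-0.14) and COPD replicate 8 (-0.078). Without control 1 (-0.49), control 2 (-0.38), control 3 (-0.42) and COPD replicate 5 (-0.53), the mean moved over 1.5 times. In the opposite direction the list passed without control 4 (0.30). For fibroblast markers, past in 9 of 17 alternatives (camera adjusted p 7.6e-04 to 0.98), the call ended with no filter (-0.31), without _x_at and _s_at probe sets (-0.14), with the hybridization covariate (-0.32), with 3 deposition groups (-0.18), and without control 3 (-0.30), control 4 (-0.023), COPD replicate 6 (-0.23) and COPD replicate 8 (-0.14). Without control 1 (-0.53) and COPD replicate 5 (-0.56), the mean moved over 1.5 times. Without control 4, THBS2 was -0.35, POSTN -0.20, THBS4 1.02, C1R -0.52, SFRP4 -0.40, C1S -0.26 and C3 -0.16, and without COPD replicate 5, TIMP3 was -0.79, THBS4 0.15 and C1R -1.26, and without control 1, C1S was -0.97 and C3 -0.96, and without COPD replicate 8, TIMP3 was -0.0011. With probe sets averaged, TIMP3 was -0.13, and with the run block, THBS2 was -1.75, POSTN -2.07, THBS4 0.0048, SFRP4 -1.46, C1S -0.94 and C3 -0.87.

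Markers of endothelium, mast cells and mesothelium, the serosal surface layer, were lower as lists. Endothelial markers had a mean of -0.29 with 15 of 17 measured genes below 0 (camera adjusted p = 6.6e-04, or 0.63 as adjusted p with an estimated correlation), with the junction protein CLDN5 (-1.02, SE 0.32), ICAM2 (-0.53), the VEGF receptor FLT1 (-0.38, 1 of 2 probe sets with this sign) and SOX18 (lower by at least 0.93, 1 of 3 COPD values at the floor). Mast cell markers had -0.47 with 5 of 6 measured genes below 0 (camera adjusted p = 0.0043, or 0.63 as adjusted p with an estimated correlation). KIT passed when adjusted over the list alone, and TPSAB1 (-0.76), TPSB2 (-0.37) and CPA3 (-0.12) did not. Mesothelial markers had -0.57 with 8 of 9 measured genes below 0 (camera adjusted p = 0.018, or 0.63 as adjusted p with an estimated correlation), with KRT18 (-1.07), KRT8 (-0.78) and SLPI (-0.74). WT1 lay at the floor in 3 of 3 COPD arrays and 1 of 4 controls, so its log2 difference rests on the floor: -1.59 (limma adjusted p = 0.9996), and -0.44 with the higher floor. Within the earlier run, within the later run and with the run as a block the means were -0.25, -0.52 and -0.38 for endothelial, -0.54, -0.78 and -0.65 for mast cell and -0.33, -1.30 and -0.78 for mesothelial markers. For endothelial markers, past in 15 of 17 alternatives (camera adjusted p 2.1e-05 to 0.18), the call ended with 3 deposition groups (-0.25), and without control 4 (-0.21). For mast cell markers, past in 14 of 16 alternatives (camera adjusted p 8.6e-04 to 0.17), the call ended with 3 deposition groups (-0.54), and without control 4 (-0.33). For mesothelial markers, past in 9 of 16 alternatives (camera adjusted p 2.3e-05 to 0.52), the call ended with no filter (-0.50), with the stricter filter (-0.50), with 3 deposition groups (-0.33), and without control 2 (-0.35), control 4 (-0.33), COPD replicate 6 (-0.57) and COPD replicate 8 (-0.45). Without control 1 (-0.94), the mean moved over 1.5 times. Without COPD replicate 8, SOX18 was -0.35, KRT8 -0.41 and SLPI -0.41, and without control 4, TPSB2 was -0.23, CPA3 -0.032 and KRT18 -0.67, and without COPD replicate 6, SOX18 was -1.51 and KIT -0.95, and without control 2, CPA3 was -0.20, and without control 1, SLPI was -1.16, and with the higher floor, SOX18 was -0.31. With probe sets averaged, FLT1 was -0.044, and without _x_at and _s_at probe sets, FLT1 was 0.29.

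Macrophage markers had a mean of -0.22 with 9 of 13 measured genes below 0 (camera adjusted p = 0.042, or 0.63 as adjusted p with an estimated correlation), with CD74 (-0.57), CSF1R (-0.41), LYZ (-0.80) and C1QA (-0.71). Neutrophil markers had -0.37 with 4 of 6 measured genes below 0 (camera adjusted p = 0.043, or 0.63 as adjusted p with an estimated correlation), with S100A9 (-1.23), S100A8 (-1.31), S100A12 (-0.27) and FPR2 (higher by at least 0.61, 1 of 4 controls at the floor). Adipocyte markers were higher, at 0.40 with 8 of 10 measured genes above 0 (camera adjusted p = 0.029, or 0.63 as adjusted p with an estimated correlation), with CIDEC (0.60), GPD1, ADIPOQ (0.85) and CIDEA (0.39). Ribosomal protein genes had -0.085 with 38 of 49 measured genes below 0 (camera adjusted p = 0.033, or 0.63 as adjusted p with an estimated correlation), with RPS9 (-0.41), RPL3 (-0.52), RPS4X (-0.25) and RPL8 (-0.36). In each of these lists 0 members passed when adjusted over the list alone. With each run taken alone (earlier, then later) and with the run as a block, the means were 0.19, -0.80 and -0.28 for macrophage, -0.18, -0.78 and -0.46 for neutrophil, 0.35, 1.15 and 0.73 for adipocyte and 0.12, -0.21 and -0.036 for ribosomal genes. For macrophage markers, past in 8 of 17 alternatives (camera adjusted p 0.0033 to 0.69), the call ended with trimmed mean scaling (-0.18), with the higher floor (-0.19), with no filter (-0.20), with probe sets averaged (-0.21), with the hybridization covariate (-0.20), with 3 deposition groups (0.19), and without control 1 (-0.23), control 4 (-0.063) and COPD replicate 8 (0.051). Without COPD replicate 5 (-0.36) and COPD replicate 6 (-0.34), the mean moved over 1.5 times. For neutrophil markers, past in 8 of 15 alternatives (camera adjusted p 0.010 to 0.56), the call ended with the run block (-0.46), with the hybridization covariate (-0.38), with 3 deposition groups (-0.18), and without control 4 (-0.25), COPD replicate 5 (-0.39), COPD replicate 6 (-0.40) and COPD replicate 8 (-0.33). For adipocyte markers, past in 11 of 17 alternatives (camera adjusted p 1.2e-04 to 0.64), the call ended with the higher floor (0.28), with no filter (0.35), with 3 deposition groups (0.35), and without control 4 (0.11), COPD replicate 6 (0.28) and COPD replicate 8 (0.18). Without COPD replicate 5 (0.75), the mean moved over 1.5 times. For ribosomal genes, past in 6 of 18 alternatives (camera adjusted p 2.5e-04 to 0.64), the call ended with no filter (-0.069), with probe sets averaged (-0.064), without _x_at and _s_at probe sets (-0.054), with the run block (-0.036), with the hybridization covariate (-0.078), with the other-cell covariate (-0.096), and without control 1 (-0.078), control 3 (-0.059), control 4 (-0.075), COPD replicate 5 (-0.043) and COPD replicate 8 (-0.032). With trimmed mean scaling (-0.16), and without COPD replicate 6 (-0.18), the mean moved over 1.5 times. In the opposite direction the list passed with 3 deposition groups (0.12). Without COPD replicate 8, LYZ was -0.42, C1QA -0.17, ADIPOQ 0.29, RPS9 -0.19 and RPL8 -0.10, and without control 4, CD74 was -0.37, FPR2 0.97 and RPL3 -0.23, and without COPD replicate 6, CIDEA was 0.14, RPS9 -0.62 and RPL8 -0.62, and without COPD replicate 5, C1QA was -1.10 and ADIPOQ 1.44, and without control 1, S100A12 was -0.15 and FPR2 0.22, and without control 3, S100A12 was -0.47, and with the higher floor, FPR2 was 0.12 and CIDEA 0.23. With the run block, FPR2 was 0.19 and RPL8 -0.19.

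**Figure D2:**
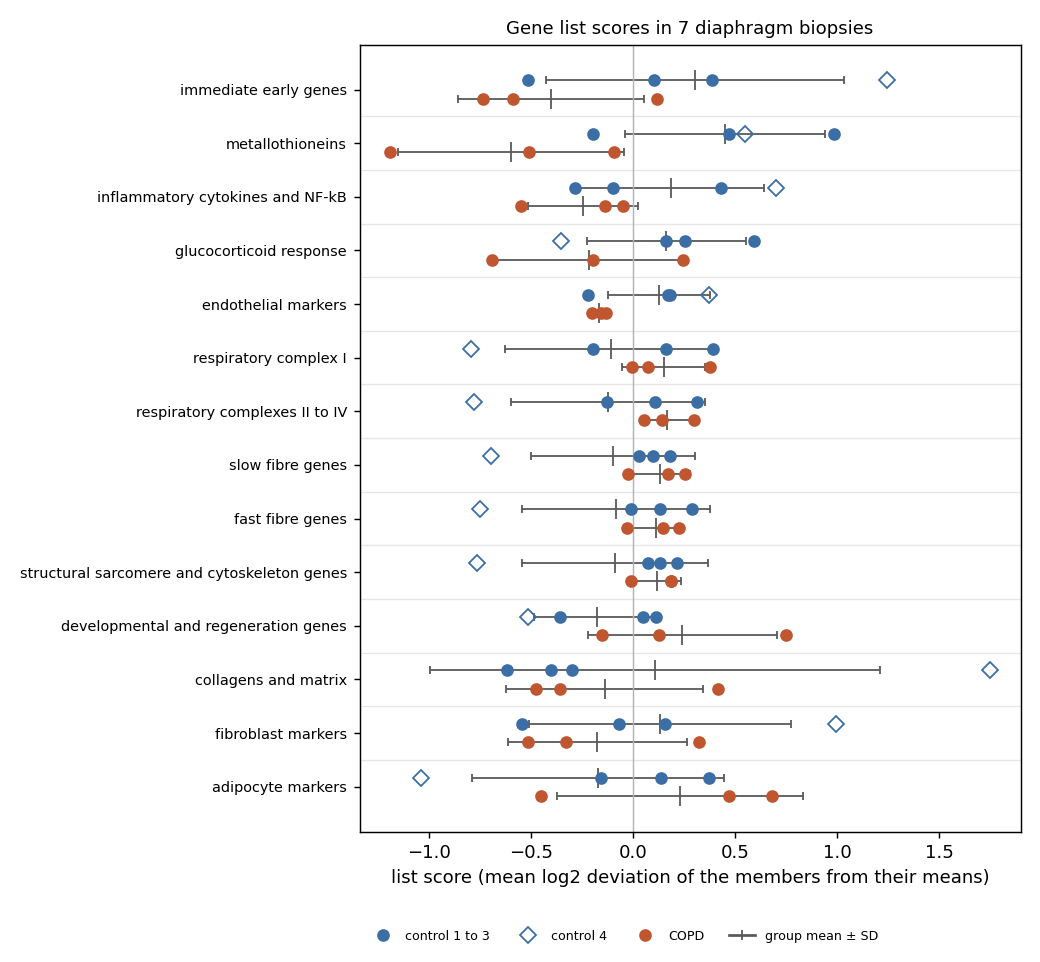
List score (x axis, mean log2 deviation of a list's genes from their means) of 14 gene lists (y axis) in each array, with bars for group mean ± SD and an open diamond for control 4. Control 4 lay at 1.75 for collagens and matrix and at -0.77 for the sarcomere list, away from the other 3 controls.

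Protein breakdown genes did not pass as lists, with means of 0.039 for the proteasome, -0.11 for atrophy and FOXO genes, -0.049 for autophagy and lysosome and -0.058 for calpains and caspases. In the atrophy list, the cathepsin CTSL stood at -0.86 and SMAD3 at 0.51. Means of the other metabolic and signalling lists that did not pass were 0.23 for creatine and adenylate kinases, 0.14 for the citric acid cycle, 0.16 for calcium handling, -0.14 for growth factor signalling, -0.12 for hypoxia, -0.020 for antioxidant and -0.0090 for clock genes. Among cell type markers that did not pass, means were -0.22 for smooth muscle, 0.20 for erythrocytes, 0.15 for lung and liver, -0.033 for T and NK cells and -0.072 for B cells. Camera's adjusted p over these lists ran from 0.054 to 0.87. The median of the autophagy, clock and B cell lists had the opposite sign to the mean, and the B cell test pointed up.

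In all, 23 of 40 lists passed at the preset correlation, 10 higher and 13 lower in COPD, and 0 passed with an estimated correlation or with fry. The number was 4 without control 4, 14 without COPD replicate 6 and 12 without COPD replicate 8, 12 without the filter and 8 without _x_at and _s_at probe sets. The 4 lists without control 4 were the immediate early, metallothionein and glucocorticoid lists in their direction and the matrix list with its direction turned, and 0 of them passed with an estimated correlation. With 3 deposition groups as a block, 5 lists passed: the immediate early list, the NF-kB list and the 2 lists of respiratory complexes in their direction, and the ribosomal list with its direction turned. With the mean score of the 12 lists of other cell types as a covariate, the metallothionein, immediate early and glucocorticoid lists passed, in their direction. With an estimated correlation 0 lists passed in any alternative (lowest adjusted p 0.47).

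Signs of RNA integrity did not differ detectably between the groups. The log2 ratio of the 3' to the 5' probe set of GAPDH was -0.38 ± 0.081 (SD, n = 3) in COPD and -0.35 ± 0.12 (SD, n = 4) in controls (exact permutation p = 0.69). For beta-actin it was -0.70 ± 0.097 and -0.44 ± 0.43 (exact permutation p = 0.46), with control 4 at 0.14 and the other controls at -0.81 to -0.38. Within the earlier and the later run the differences were 0.063 and -0.13 for GAPDH and -0.077 and -0.84 for beta-actin. The hybridization controls averaged 10.19 ± 0.67 in COPD and 10.13 ± 0.40 in controls on the log2 scale (exact permutation p = 0.86).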

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

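The tests of explanations in this part were chosen after the results were seen. Among the 4 controls, 8 of 67 values (list scores, named genes and single measures) had 1 array further from the rest than Dixon's 95% critical value allows. Chance gives about 1 in 20 for independent values. These come from the same 4 arrays and are not independent, so the count is not a test against chance. In 6 of the 8 the array was control 4. Its gap as a share of the range was 0.856 (-0.77 against 0.071 to 0.21) for the sarcomere score, 0.884 (-0.81 against 0.096 to 0.21) for glycolysis and glycogen, 0.855 (-0.79 against 0.074 to 0.22) for creatine and adenylate kinases, 0.902 (-0.22 against 0.069 to 0.10) for antioxidant genes, 0.835 (-0.46 against -0.037 to 0.046) for chaperones and 0.865 (1.75 against -0.62 to -0.30) for collagens and matrix. FAM86C1P is not counted among these: its share is 1 by construction, since 3 controls lie at the floor and control 4 at 4.74. CEBPD was high in control 2, with a share of 0.849 (11.52 against 10.37 to 10.54). The slow minus fast index was low in control 3, with a share of 0.836 (0.44 against 0.75 to 0.81).

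Over 7 muscle, respiratory and metabolic lists the mean difference was 0.24 with all arrays, 0.0045 without control 4 (-0.11 to 0.067 by list) and 0.22 to 0.36 without any other array, and the matrix list went from -0.25 to 0.30 without control 4 and ran from -0.53 to -0.078 without any other, which is consistent with control 4 setting these 8. With the mean score of 12 lists of other cell types as a term, the 7 lists averaged -0.028 (-0.13 to 0.021 by list) and the matrix list was 0.29, which is also consistent with a different share of non-muscle cells, but that score was itself highest in control 4 (0.27), while the developmental list was 0.31 against 0.42 without control 4 and 0.30 with this term (camera adjusted p = 0.065 and 0.13) and was 0.17 without COPD replicate 5, its call ended in each, so for this list neither can be told apart from a difference between the groups. The tables argue against a run that control 4 shares with COPD replicates 5 and 8 as the whole of its shift. Over the 9 lists control 4 differed from the other controls by 1.01. These replicates differed from replicate 6 by a mean of 0.0049 in that direction (-0.59 to 0.35 by list). That mean holds lists of opposite sign and rests on replicate 6 alone, so a smaller run shift is not excluded. In control 4, 9 of 12 lists of other cell types lay above every other control, 4 of them by over 2 SDs from their mean. Adipocyte markers lay -1.16 from the mean of the other controls (SD 0.27) and erythrocyte markers, with 5 measured genes, -0.64 (SD 0.24). Of the 10 measured adipocyte markers, the 4 of smallest p between the groups disagreed in control 4. CIDEC (7.83) and CIDEA (6.67) lay above every other control, and ADIPOQ (6.89) and GPD1 (4.71) below. GPD1 is also in the glycolysis list, and in control 2 (4.78) it was nearly as low, near the floor of 4.55. The score of -1.16 rests on all 10 markers. The adipocyte and erythrocyte scores go against a smaller muscle share that raised every other type alike. They come from control 4 alone, so this is not decided. A smaller muscle share, with or without fewer adipocytes, and a change in connective tissue (fibroblast markers 1.15) stay open. By the labels control 4 shares its group and kind of surgery with the other controls, so neither accounts for its distance from them. COPD and the kind of surgery stay open as untested for the developmental list. Neither a deposition of its own nor lower RNA quality can be told apart from control 4 itself. Its 3' over 5' ratio lay 0.77 above the other controls for beta-actin (SD 0.23) and 0.087 for GAPDH (SD 0.13).

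The metallothionein list differed by -1.05 (95% interval -2.06 to -0.036). The difference was -1.02 (-2.33 to 0.28) without control 4, -0.93 (-2.22 to 0.36) with the run as a term, and -0.88 (-2.19 to 0.42) with the mean score of 12 lists of other cell types as a term. The tables argue against control 4 as the whole cause, since the difference hardly moved without it (camera adjusted p = 2.4e-07, or 0.86 with an estimated correlation). With the run and with the other-cell score most of it stayed (camera adjusted p = 1.3e-04 and 1.7e-05, or 0.49 and 0.99 with an estimated correlation). But these intervals between arrays hold 0, and the other-cell score averages lists that moved opposite ways in control 4. So neither the run nor the share of non-muscle cells can be told apart from a difference between the groups. The matrix list moved from -0.25 to 0.30, -0.80 and 0.29 under the same changes. The score of control 4, the only control of the later run, was 0.55 and lay within those of the other controls (-0.20 to 0.98), and the difference was -0.51 within the earlier and -1.40 within the later run. A separate level in each of 3 deposition groups cannot be told apart from a difference between the groups, since COPD replicates 5 and 8 share theirs with no control and the rest is 1 COPD array at -0.51 (-2.57 to 1.54), and shared probe sequence, COPD and the kind of surgery stay open as untested.

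The immediate early list differed by -0.71 (95% interval -1.95 to 0.54), and by -0.40 (-1.45 to 0.65) without control 4 (adjusted p = 6.3e-05, or 0.86 with an estimated correlation). The list stayed below 0 without control 4, but that value exceeds its SE by little and its interval holds 0. With genes and probe sets chosen anew it was -0.34. So control 4 as the cause cannot be told apart from a difference between the groups. The matrix list moved from -0.25 to 0.30 without control 4. With the mean score of other cell types as a term it was -0.32 (-1.58 to 0.95), within its SE of 0 though past camera's threshold (adjusted p = 0.0057, or 0.99 with an estimated correlation), so fewer non-muscle cells cannot be told apart from a difference between the groups. With the run as a term it was -1.04 (-2.27 to 0.20), past camera's threshold (adjusted p = 5.9e-13, or 0.49 with an estimated correlation), but control 4, the only control of the later run, scored 1.24 against -0.51 to 0.38 in the other controls, which makes the difference -1.56 within that run and -0.58 within the earlier one, so the run cannot be told apart from a difference between the groups. A separate level in each of 3 deposition groups cannot be told apart from a difference between the groups here either, since -0.58 (-2.46 to 1.30) stayed, within its SE of 0 and from 1 COPD array, though past camera's threshold (adjusted p = 1.0e-04, or 0.93 with an estimated correlation), and COPD and the kind of surgery stay open as untested.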

How the results depend on the processing

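The hybridization control covariate, the block of 3 deposition groups, the other-cell covariate, camera without variance trend, the exact permutation of list scores and the quantile setting for RNA quality were added after the data were seen, and so was the choice to hold genes and probe sets with 1 array left out. Ranges with 1 array left out cover both the held and the anew choice, in which 46 to 81 genes changed probe set and 165 to 204 left the set. The count of limma genes past adjusted p was 2 without the filter and 0 in the other settings. The 2 of 11938 were FAM86C1P and ZNF350 (adjusted p = 0.045 for both), with 3 and 4 of 4 controls at the floor, and ZNF350 was chosen after its values were seen. The count at unadjusted p under 0.05 was 401 without the filter, 129 without _x_at and _s_at probe sets, 649 with the run as a block, 339 per probe set, 520 with array weights and 151 to 394 with 1 array left out. Lists past camera numbered 12 without the filter, 8 without _x_at and _s_at probe sets, 5 with 3 deposition groups, 3 with the other-cell covariate, 0 with an estimated correlation, fry or permuted scores, and 4 to 25 with 1 array left out. Of the 23 lists, trimmed mean scaling kept the direction and call of 18 and the run block of 20. Leaving out control 4 kept those of 3. Control 4 is the only control of the later run, so the run block gives it more weight. With that block complex I went from 0.26 to 0.53, the matrix list from -0.25 to -0.80 and the glucocorticoid list from -0.38 to -0.092. A call kept there does not separate the run from control 4. The median difference of all genes was 0.021 with quantile and 0.026 with trimmed mean scaling. With 1 array left out, means ran from -0.020 to 0.30 for sarcomere, -0.11 to 0.34 for fatty acid, -0.033 to 0.31 for glycolysis, -0.53 to 0.30 for matrix and -0.026 to 0.32 for fast fibre genes, whose test turned without control 4. For fibroblast markers the means ran from -0.56 to -0.023, and camera's direction but not the mean turned without control 4. They ran from 0.011 to 0.36 for chaperones, where camera's direction but not the mean turned without COPD replicate 5, and -0.36 to 0.051 for macrophage markers, turned without replicate 8. With 3 deposition groups, means were -0.13 for slow, -0.17 for fast, -0.15 for sarcomere, -0.086 for developmental, -0.044 for fatty acid, -0.020 for glycolysis, -0.11 for chaperone, 0.082 for matrix, 0.19 for macrophage and 0.12 for ribosomal genes, each turned, in a fit that rests on COPD replicate 6 alone. With the other-cell covariate, means were -0.063 for complex I, -0.00075 for ATP synthase, -0.13 for fatty acid, -0.036 for glycolysis, -0.044 for fast and 0.29 for matrix genes, each turned. The slow minus fast difference was -0.0030 with probe sets averaged, -0.0081 without _x_at and _s_at probe sets, -0.017 with medians and -0.047 to 0.11 with 1 array left out. The GAPDH difference ran from -0.085 to 0.014 and that of beta-actin from -0.39 to -0.070 with 1 array left out. Without _x_at and _s_at probe sets, which swaps the probe set, NR4A1 was 0.61, ATP2A2 -0.14, MT1G 0.17 and FLT1 0.29, and APAF1 ran from -1.57 to 0.13 with 1 array left out. Chosen anew, GADD45B was -0.26 without control 4 and GPD1 0.46 without COPD replicate 8, each from another probe set. With that choice the neutrophil list was -0.58 without COPD replicate 5 and -0.48 without replicate 8, past camera's threshold in both (adjusted p = 0.021 and 0.044, or 0.54 and 0.81 with an estimated correlation), where the held choice ended the call, and the fast list passed without control 2 (0.049, or 0.71 with an estimated correlation). The cause of the other changes was not tested. Signal near the floor limits genes of low intensity. No paired analysis was possible because the groups share no replicate numbers. Values within a run, which holds 1 COPD array in the earlier and 1 control in the later one, were not tested, but the block of 3 groups tests the contrast of the earlier run, assuming that its 1 COPD array varies like the others.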

Other observations

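The tests of other splits in this part were chosen after the results were seen. Control 4 differed from the mean of the other 3 controls over most muscle lists: by -1.26 for fatty acid genes, -1.17 for the citric acid cycle, -0.96 for glycolysis, -0.91 for complex I, -0.89 for fast and -0.80 for slow fibre genes. It was 2.19 above them for the matrix list and 1.25 above for immediate early genes. COPD replicate 5 had the highest scores of the 7 arrays for developmental genes (0.75) and chaperones (0.61).

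The 7 arrays can be split into 3 and 4 in 35 ways. As limma gave 0 genes in the real comparison (210 at unadjusted p under 0.05), all 35 splits give at least as many by construction, so the count of splits decides nothing about chance. The highest other count was 2, in the split of control 4 and COPD replicates 5 and 8, and with that run as a block the real comparison gave 0. The split of control 1, control 3 and COPD replicate 6 from the rest gave 1583 genes at unadjusted p under 0.05, against 210 in the real one. It was picked as the highest of the 35, so this count does not by itself show a structure of the arrays. The run split gave 1106. For lists past camera's threshold, 4 of the 35 splits, the real one included, gave at least 23, and the highest other gave 26, so chance is not excluded.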
